A study of Homo sapiens with 9 samples.

How the data were processed

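The data were 8 peak lists from ChIP-seq of A673/TR/shEF cells, 6 for FLI1 (days 7, 9, 10, 11, 14 and 17) and 2 for H3K27ac (days 0 and 7), each from 1 library. The day 0 input library was not analysed here. Per the labels' protocols, chromatin was crosslinked with paraformaldehyde and sequenced as 100 bp single-end reads. Per the submitters' processing notes, reads were aligned with Bowtie2 to hg19 and MACS2 version 2.0.10 was used. The authors called peaks per sample, going by the file contents: narrow peaks for FLI1 (10 columns) and broad peaks for H3K27ac (9 columns). The peak names of all lists carry the same second identifier, from which 1 common control is inferred. The numbering of the peaks has gaps of at least 4 to 21 peaks per list, and the file names speak of a cleaned list. What was removed is not given in the sources used here.

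The deposited files give for each peak a score, which is 10 times the −log10 q for at least 99.99% of peaks in each list, a fold enrichment, a ratio whose FLI1 values fit reads over expected background with a pseudocount of 1, and the −log10 p-value and −log10 q-value. These are the authors' values for each peak. Folds and scores were used to describe, rank or filter peaks within a list. The −log10 p-values were also held to a common minimum across lists in the settings that say so. Summit positions are those deposited with the FLI1 lists. The smallest −log10 p in a FLI1 list ranged from 3.72 at day 14 to 5.53 at day 9, so the lists were not cut at 1 common p.

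Peaks were compared by overlap of at least 1 bp with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The overlap code was checked against bedtools 2.31.1, which gave the same numbers. The FLI1 lists were merged where they overlapped, and each region was given the first day on which it was seen. H3K27ac peaks were classed as day 0 only, day 7 only or shared. A FLI1 peak or region was placed in day 0 only H3K27ac where it overlapped a day 0 and no day 7 peak. Day 7 only was the reverse. Such a FLI1 peak can lie in a shared H3K27ac peak, in the part marked on 1 day. Shares have Wilson 95% intervals and summits per Mb have exact Poisson 95% intervals, from scipy 1.17.1. Both cover counting error only, since each group has 1 library. The share expected for unrelated positions was the mean over 100 shifts of the peaks by 100 kb to 1 Mb. It does not reproduce a control shared by the lists.

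Depth was recovered for FLI1 lists from the deposited fold and −log10 p-value, which together fix the number of reads at a summit. Between 99.8% and 100% of peaks per list gave a whole number with an error in −log10 p under 0.001. The lowest background in a list, divided by its shortest peak width, taken as the fragment length, gave the relative depth. On 5000 simulated peaks with known pileups, 100% were recovered, and 0.92% of 5000 simulated pileups that were not whole passed as whole. On 5000 simulated peaks, 100% of planted overlaps were called as planted. Broad peak lists hold means over a region and gave no depth.

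Regions named in the text follow a rule fixed before the data were examined: the 10 FLI1 regions without a day 7 peak with the highest fold at day 17, the 5 day 7 FLI1 peaks with the highest fold, and the 10 widest H3K27ac peaks of either single-day class. Chromosome Y, mitochondrial and unplaced sequence were not to be named. Comparisons were also fixed then, as were the settings to vary. They were a −log10 q of at least 5, an overlap of at least 50% of the shorter peak, a gap of up to 500 bp, equal numbers of peaks, covered base pairs in place of peak numbers, merging of peaks within 1 kb, autosomes and X only, and days of the first library set only. Added after the data were seen were a common p minimum, thinning of the recovered pileups to equal depth (100 draws), stricter peaks of 1 day against all peaks of another, weighting to equal width and strength (rank of the fold within its list), and leaving out chromosome 19. Library sets were read from the prefixes of the file names: days 7, 11, 14 and 17 of FLI1 form the first, and days 9 and 10 of FLI1 with both H3K27ac lists the second. Figures were drawn with matplotlib 3.10.9.

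An hg19 sequence or annotation was not used here. The planned GGAA repeat content of peaks, the split into promoter and distal sites and both planned comparisons of gene lists were therefore not run, no gene was assigned to a peak, and regions are named by position alone.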

Results

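The series followed binding of EWSR1-FLI1, the fusion transcription factor of Ewing sarcoma, in A673/TR/shEF cells, a derivative of the Ewing sarcoma line A673 that carries a doxycycline-inducible hairpin RNA against the fusion. Doxycycline (DOX) was present for 7 days and was then washed out, so that the hairpin was switched off and the fusion could return. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with a FLI1 antibody on days 7, 9, 10, 11, 14 and 17. The same assay was done for H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, on day 0 before DOX and on day 7. Each of these 8 groups held 1 library, as did the day 0 input, so no difference below was tested against replicates and no p-value between days is given. Intervals are 95% intervals of counting error within a list. Library totals were not used here. For the FLI1 lists, the read background recovered from the peak values put the relative depth at 0.831 for day 9, 0.719 for day 10, 1.10 for day 11, 0.750 for day 14 and 0.943 for day 17, with day 7 set to 1. The depth of both H3K27ac libraries is unknown.

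The first comparison asked how many FLI1 peaks were called on each day. Neither the amount of the fusion nor the yield of each immunoprecipitation was analysed here, and both can bear on a peak number. At day 7, at the end of the knockdown, 4324 FLI1 peaks were called. The lists of days 9 and 10 were shorter, with 1199 and 1591 peaks, or 0.277 and 0.368 times the day 7 number. Day 11 had 18848 peaks, 11.8 times as many as day 10, and the number went on to 22517 at day 14 and 26618 at day 17, which was 6.16 times that of day 7. Peaks covered 1.26 Mb at day 7, 0.322 Mb at day 9, 6.05 Mb at day 11 and 10.7 Mb at day 17, and their median width was 264 bp at day 7 and 341 bp at day 17. Days 9 and 10 came from another library set than days 7, 11, 14 and 17, going by the file names, so that day and library set cannot be told apart for the dip. Within the first set the number rose on each later day, and within the second set it was 1.33 times higher at day 10 than at day 9.

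**Figure D1:**
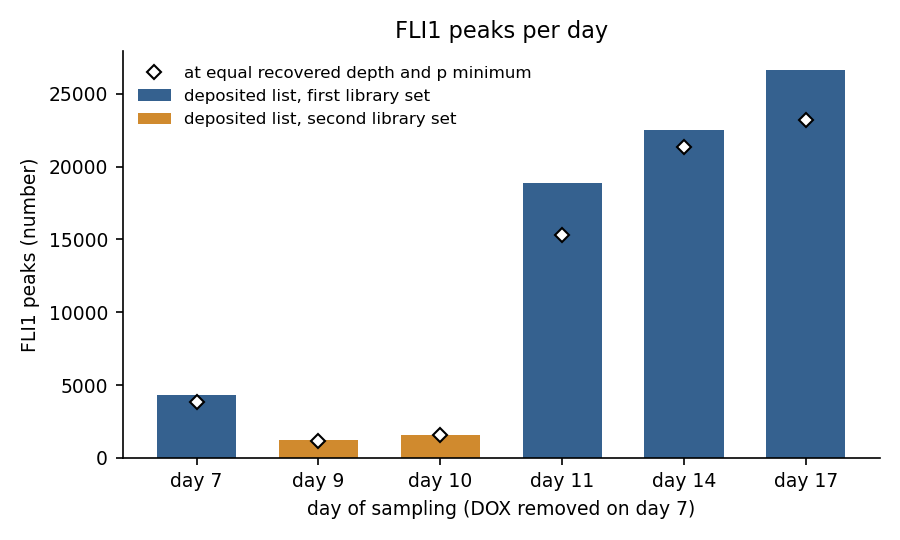
Number of FLI1 peaks (y axis) on each day (x axis), with 1 library per day; bars are the deposited lists, coloured by library set, and diamonds are the mean number left after thinning each list to the depth of day 10 at 1 common p minimum. The lists grow from 4324 peaks at day 7 to 26618 at day 17, with 1199 and 1591 peaks at days 9 and 10, and the diamonds keep that order.

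The second comparison asked when the sites of day 17 were first seen. Of the 26618 day 17 peaks, 10.3% (9.91 to 10.6) were overlapped by a day 7 peak, 3.77% (3.55 to 4.004) by a day 9 peak and 4.95% (4.69 to 5.21) by a day 10 peak. The share was 42.6% (42.0 to 43.1) for day 11 and 65.5% (64.9 to 66.1) for day 14. Peaks moved to nearby positions were overlapped in at most 0.845% of cases. Strong day 17 peaks were overlapped on earlier days more often than weak ones. In the 10% of the day 17 list with the highest fold enrichment, 88.2% of peaks were overlapped at day 11 and 27.3% at day 7, against 18.7% and 4.02% in the lowest 10%. Most peaks of the short lists lay at sites seen on other days: 86.9% of day 9 peaks and 77.9% of day 10 peaks overlapped a day 7 peak, and 99.0% of either list overlapped a day 11 peak. When each list was held to its 1199 strongest peaks, the shares of day 17 peaks seen at days 7, 9 and 10 were 18.7%, 20.7% and 20.7%. All lists appear to share 1 control, which can itself add to these overlaps.

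**Figure D2:**
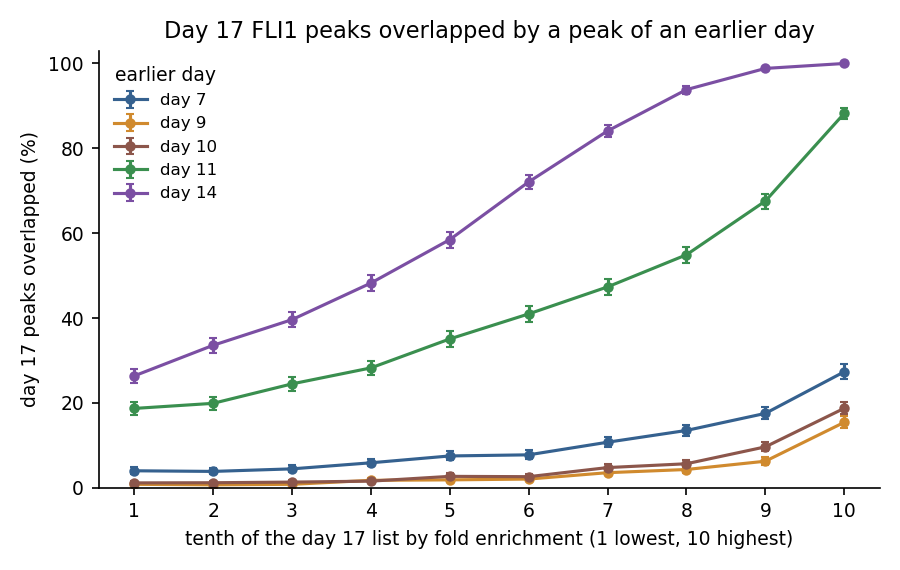
Share of day 17 FLI1 peaks (y axis, percent) overlapped by a peak of days 7, 9, 10, 11 or 14, for 10 equal classes of the day 17 list ordered by the fold enrichment given by the authors (x axis); points are shares in 1 library per day and bars are 95% Wilson intervals. For day 11 the share is 18.7% in the lowest class and 88.2% in the highest.

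Merging the 6 lists gave 37696 FLI1 regions. Of these, 4303 were present at day 7 and 33393 were first seen later. The largest number, 14440, was first seen at day 11, followed by 10486 at day 14 and 8034 at day 17, while 153 and 280 were first seen at days 9 and 10. Regions seen at day 7 were mostly present at day 11 (88.0%) and less often at day 17 (63.5%). Of the regions first seen at day 11, 57.6% were present at day 17. A total of 699 regions were present on all 6 days and 16786 on 1 day only. With 1199 peaks from each list, 2010 regions were first seen after day 7, and the order of the days changed. There were 513 at day 9, 332 at day 10, 393 at day 11, 538 at day 14 and 234 at day 17. This cut kept the whole day 9 list but only 1199 of the 4324 day 7 peaks. A region with a weaker day 7 peak thus counts as first seen later. In the whole lists, 1042 of the 1199 day 9 peaks overlapped a day 7 peak. The changed order therefore does not date the sites.

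Among regions without a day 7 peak, the 10 with the highest fold enrichment at day 17 ranged from 75.4 to 87.7 in that list. The highest lay on chromosome 4 at 147411940 to 147413574 (hg19, as are all positions here) with a fold of 87.7, and was first seen at day 10. The other 9 were first seen at day 11, and all 10 were present at days 11, 14 and 17. A region on chromosome 6 at 136154296 to 136155519, with a fold of 85.0, overlapped no H3K27ac peak on either day. Regions on chromosome 14 at 97681497 to 97682539 (81.9), chromosome 10 at 24678875 to 24680019 (81.3), chromosome 12 at 45279352 to 45280283 (77.7) and chromosome 15 at 78029782 to 78032180 (77.2) overlapped H3K27ac at day 0 and not at day 7. The other 5, among them one on chromosome 22 at 30831385 to 30832643 (81.7), were acetylated on both days. The 5 strongest peaks of day 7 had folds of 31.9 to 57.3 in the day 7 list and were present on all 6 days. The first of them, on chromosome 4 at 2414706 to 2415306, ranked 2022 in the day 17 list. All 5 overlapped H3K27ac at day 7 and 4 of them at day 0 also, the exception being the peak on chromosome 4 at 26198965 to 26199388.

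The third comparison set H3K27ac before the knockdown against its end. Day 0 had 53522 broad peaks over 207 Mb and day 7 had 69687 over 229 Mb, with median widths of 2164 and 1982 bp. Of the day 0 peaks, 15078 or 28.2% (27.8 to 28.6) overlapped no day 7 peak, and of the day 7 peaks, 30330 or 43.5% (43.2 to 43.9) overlapped no day 0 peak. Peaks of 1 day only were narrower than shared ones. Their median width was 1450 bp at day 0 and 1428 bp at day 7, against 2539 bp and 2640 bp for those with an overlap. They held 16.4% of the base pairs marked at day 0 and 26.2% of those marked at day 7. Both days shared 119 Mb. More peaks were called at day 7 than at day 0 on 22 of 23 chromosomes, the exception being chromosome 19 with 0.966 times as many. Taking the same number of peaks from both lists left 35.5% of day 0 peaks and 35.8% of day 7 peaks without an overlap. Few peaks overlapped 2 or more peaks of the other day (4.52% at day 0 and 2.61% at day 7). Lists of equal length therefore give nearly equal shares whatever the acetylation did. These values cannot tell whether the difference between 28.2% and 43.5% reflects more than list length. At a −log10 q of at least 5, the lists held 24686 and 43284 peaks and the shares without a stricter overlap were 16.4% and 50.1%. Many of these stricter peaks overlapped a weaker peak of the other day. Only 8.26% and 29.8% of the stricter peaks overlapped no peak of the other day at all.

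The fourth comparison asked which of these regions FLI1 occupied. At day 7, 94.1% of FLI1 peaks lay in H3K27ac of day 7, 71.0% (69.7 to 72.4) where both days were marked and 23.1% (21.8 to 24.4) where day 7 alone was. Only 0.786% (0.563 to 1.10) lay in H3K27ac of day 0 alone. At days 9 and 10 the order of both single-day classes was as at day 7, with 0.5004% and 0.629% in day 0 only against 15.8% and 15.4% in day 7 only H3K27ac. It was still so at day 11 and was the other way at days 14 and 17. The share in day 0 only H3K27ac was 6.88% (6.53 to 7.25) at day 11, 16.1% (15.6 to 16.6) at day 14 and 18.96% (18.5 to 19.4) at day 17. The share in day 7 only H3K27ac was 18.7% (18.1 to 19.2), 8.80% (8.43 to 9.17) and 7.00% (6.70 to 7.31) on the same days. Sites marked on both days held 58.4% of day 17 peaks, and 15.7% lay in neither, a share that was 28.6% with stricter peaks and 3.67% among the 1199 strongest peaks. Moved to nearby positions, day 17 peaks fell into day 0 only H3K27ac in 4.51% of cases and into day 7 only H3K27ac in 5.37%. With stricter peaks of both kinds (−log10 q of at least 5), day 17 peaks lay in day 0 only H3K27ac 1.28 times as often as in day 7 only H3K27ac. The value was 2.71 times in the whole lists. At day 14 the order was lost, at 0.979 times (0.928 to 1.03) against 1.83. Far fewer H3K27ac peaks without a stricter overlap were left at day 0 than at day 7 (4041 against 21690). A site in these stricter classes may still be marked by a weaker peak on the other day. The stricter shares in day 0 only and day 7 only H3K27ac were 1.27% and 36.5% at day 7, 1.34% and 30.3% at day 9, 1.46% and 27.9% at day 10, and 15.9% and 12.4% at day 17. Among the 1199 strongest peaks of each list they were 0.334% and 17.9% at day 7, 4.42% and 9.76% at day 11, 19.8% and 3.84% at day 14, and 27.5% and 3.34% at day 17.

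FLI1 summits were also counted per Mb within H3K27ac peaks classed as day 0 only (34.0 Mb), day 7 only (59.9 Mb) or shared. These sets are narrower than those above, since single-day parts of shared H3K27ac peaks do not count as single-day here. At day 17, 3254 summits lay in day 0 only H3K27ac peaks, while 5048 FLI1 peaks overlapped H3K27ac of day 0 and not of day 7. In day 0 only H3K27ac there were 0.734 summits per Mb at day 7, 23.2 at day 11, 68.7 at day 14 and 95.6 (92.3 to 98.9) at day 17. In day 7 only H3K27ac there were 13.1 at day 7, 45.9 (44.2 to 47.6) at day 11, 25.4 at day 14 and 23.3 (22.1 to 24.6) at day 17. The number per Mb at day 17 was thus 4.12 times that of day 11 in the first class and 0.508 times in the second. Day 0 peaks shared with day 7 held 17.5 summits per Mb at day 7 and 97.6 at day 17. The density in day 0 only over day 7 only H3K27ac was 2.71 (2.54 to 2.89) at day 14 and 4.10 (3.85 to 4.37) at day 17, with the stricter peaks it was 2.63 and 3.41, and among the 1199 strongest FLI1 peaks of each list it was 5.86 and 9.87. Among those strongest peaks the number at day 17 was 5.27 times that of day 11 in day 0 only and 0.316 times in day 7 only H3K27ac.

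**Figure D3:**
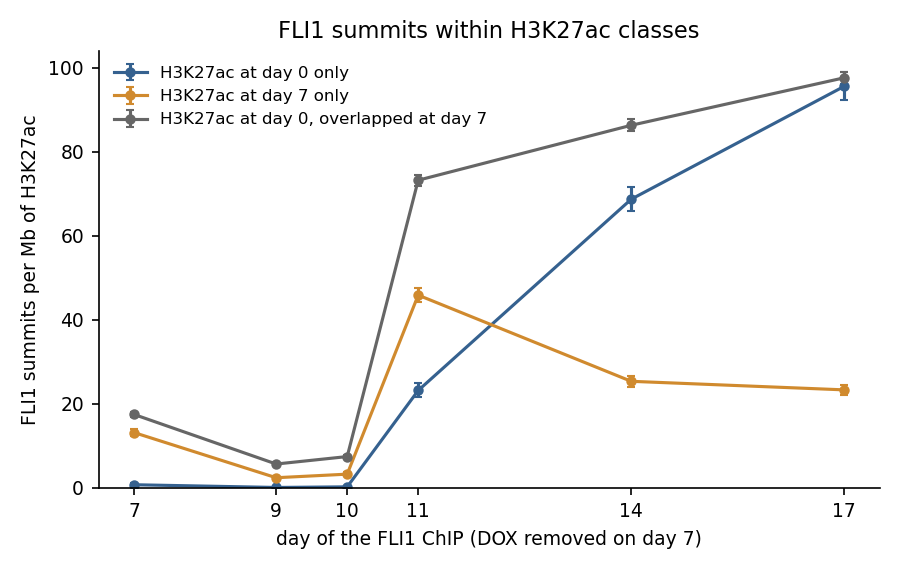
FLI1 summits per Mb (y axis) within H3K27ac peaks of day 0 only, of day 7 only, and of day 0 with a day 7 overlap, on each day of the FLI1 ChIP (x axis); points are counts in 1 library per day and bars are 95% Poisson intervals. From day 11 to day 17 the value goes from 23.2 to 95.6 in the day 0 only class and from 45.9 to 23.3 in the day 7 only class.

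Seen from the acetylated regions, 19.98% (19.4 to 20.6) of the day 0 only H3K27ac peaks held a day 17 FLI1 peak, against 4.59% (4.36 to 4.83) of the day 7 only peaks and 32.4% (31.9 to 32.8) of the shared day 0 peaks. The H3K27ac peaks of these classes, moved nearby, gave 3.09%, 2.53% and 5.19%. With stricter peaks the shares were 47.6%, 10.5% and 36.0%, so that day 0 only peaks then stood above shared ones. The stricter single-day classes include peaks that overlap a weaker peak of the other day. At day 11 the order of these classes was the other way, with 5.21% (4.87 to 5.58) of day 0 only and 8.68% (8.37 to 9.0) of day 7 only peaks holding a FLI1 peak.

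The 10 widest day 0 only H3K27ac peaks spanned 30.9 to 45.3 kb. None held a FLI1 peak at day 7, 7 of them held 9 FLI1 peaks at day 11, and 9 held 28 at day 17. The widest, on chromosome 4 at 108066105 to 108111445, held 2 FLI1 peaks at day 14 and 4 at day 17, and one on chromosome 6 at 125084778 to 125121930 held 1, 4 and 5 at days 11, 14 and 17. The exception was the peak on chromosome 16 at 24017402 to 24058449, without a FLI1 peak on any day. The 10 widest day 7 only H3K27ac peaks spanned 20.8 to 42.6 kb. Of these, 4 held a FLI1 peak at day 7, 8 held 19 FLI1 peaks at day 11, and 6 held 8 at day 17. The widest, on chromosome 20 at 49947294 to 49989879, held 1 FLI1 peak at day 7, 5 at day 11 and 1 at day 17. One on chromosome 18 at 469614 to 495486 held 3 at day 11 and 0 at day 17. The number rose on chromosome 12 at 76157584 to 76187733, from 2 at day 11 to 3 at day 17. It also rose on chromosome 9 at 4093298 to 4118905, from 0 to 1.

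**Figure D4:**
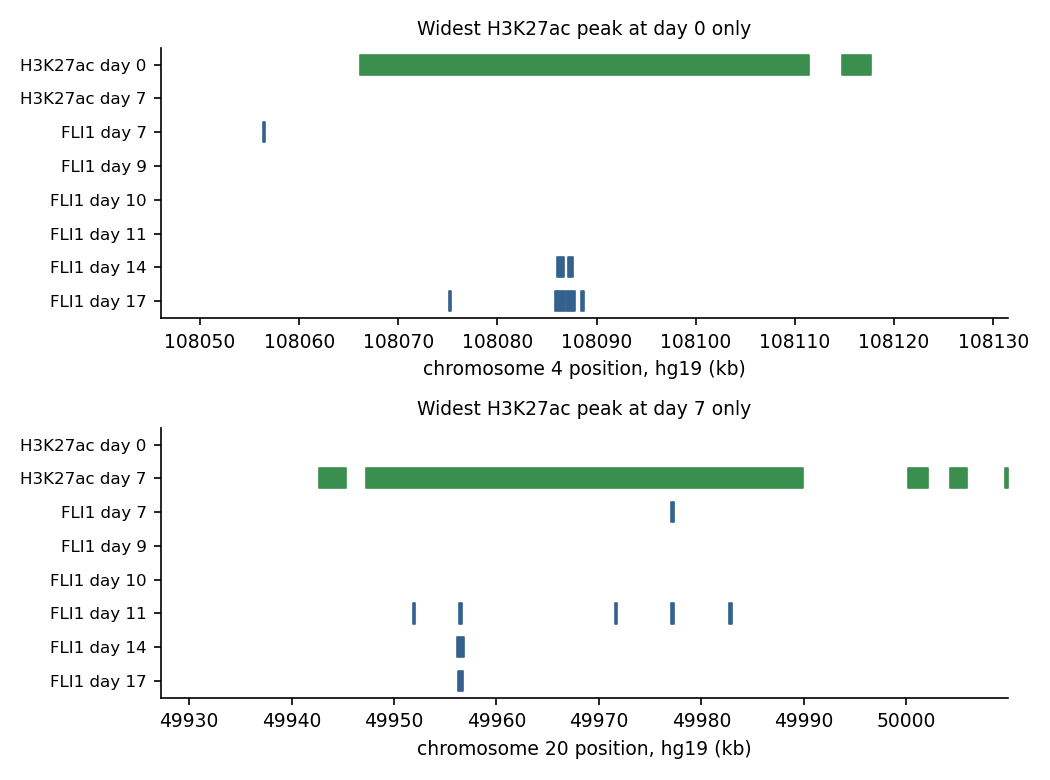
Maps to scale of the widest H3K27ac peak of day 0 only (chromosome 4, top) and of day 7 only (chromosome 20, bottom), with flanking sequence; the x axis is the hg19 position in kb, each row is 1 library, and boxes are called peaks, H3K27ac in green and FLI1 in blue. The top region holds 4 FLI1 peaks at day 17 and 0 at day 11, and the bottom one holds 5 at day 11 and 1 at day 17.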

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

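The common p minimum, equal depth, stricter peaks against all peaks, weighting and removal of chromosome 19 were chosen after seeing the data. Of 235 values under alternatives, 128 stayed within the counting interval of the reported share or ratio, or within 1.5 times a reported count. A further 106 moved more and 1 ratio crossed 1. The cause was not tested. The 128 include values that could barely move. Among them are 3 from merging within 1 kb and 11 from autosomes and X only, where the day 17 list went from 26618 to 26617 peaks. The number kept is therefore no measure of stability. FLI1 peak numbers per day stayed within 1.5 times under the stricter q, autosomes and X only, a common p minimum and equal depth. Merging within 1 kb, applied to the H3K27ac lists alone, is void, since no peaks of 1 H3K27ac list lie that close, and the GGAA and gene alternatives were not run. The unknown depth of the H3K27ac libraries limits any statement on their peak numbers.

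With a −log10 q of at least 5, H3K27ac peaks fell to 24686 at day 0 and 43284 at day 7. Those without overlap by a stricter peak of the other day were 16.4% and 50.1%, and the difference was 33.7 points. A weaker peak of the other day may overlap peaks of these single-day classes. FLI1 peaks in day 0 only H3K27ac were 1.27%, 1.34%, 1.46%, 7.60%, 14.7% and 15.9% from day 7 to day 17, and in day 7 only 36.5%, 30.3%, 27.9%, 27.3%, 15.01% and 12.4%. The ratio of day 0 only to day 7 only was 0.278 at day 11 and 1.28 at day 17, and at day 14 it was 0.979 in place of 1.83, with an interval of 0.928 to 1.03 that holds 1. Per Mb it was 0.755 at day 11 and 3.41 at day 17. H3K27ac peaks holding a day 17 FLI1 peak were 47.6% (day 0 only), 10.5% (day 7 only) and 36.0% (shared). Of day 17 FLI1 peaks, 43.1% lay in H3K27ac of both days and 28.6% in neither. FLI1 summits at day 17 over day 11 were 2.98 (day 0 only) and 0.658 (day 7 only). Day 17 peaks seen at day 14 were 67.3%.

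With an overlap of 50% of the shorter peak, H3K27ac peaks without overlap were 29.6% and 44.7%, FLI1 peaks in day 7 only H3K27ac were 19.4%, 9.29% and 7.42% at days 11, 14 and 17, day 0 only peaks with FLI1 were 18.9%, and day 17 peaks seen at day 14 were 64.9%. With a gap of 500 bp, day 17 peaks seen at days 7, 11 and 14 were 10.8%, 44.3% and 67.3%.

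With 1199 FLI1 peaks per list, day 17 peaks seen at days 7, 9, 10, 11 and 14 were 18.7%, 20.7%, 20.7%, 44.0% and 78.5%. Regions first seen after day 7 numbered 2010, beside 1196 seen at day 7. They were made up of 513 at day 9, 332 at day 10, 393 at day 11, 538 at day 14 and 234 at day 17. Day 11 no longer had the most and day 9 rose from 153. The cut drops weaker day 7 peaks and keeps the whole day 9 list, so regions with such a day 7 peak count as first seen later. FLI1 peaks at days 7, 11, 14 and 17 lay in day 0 only H3K27ac in 0.334%, 4.42%, 19.8% and 27.5%, and in day 7 only in 17.9%, 9.76%, 3.84% and 3.34%. The ratios were 0.0186, 0.453, 5.15 and 8.25, and per Mb 0.592, 5.86 and 9.87 at days 11, 14 and 17. Summits at day 17 over day 11 were 5.27 (day 0 only) and 0.316 (day 7 only).

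With equal numbers of H3K27ac peaks, 35.5% and 35.8% had no overlap, a difference of 0.256 points. Few peaks overlapped several peaks of the other day, so lists of equal length give nearly equal shares whatever the acetylation did. This setting therefore cannot tell whether the difference between the whole lists reflects more than list length. By base pairs covered by peaks without an overlap the shares were 16.4% and 26.2%, a difference of 9.78 points. Counted base by base, 57.5% of the day 0 base pairs were also marked at day 7. In the other direction the share was 52.2%. Stricter H3K27ac peaks against all peaks of the other day gave 8.26% and 29.8%, and stricter day 17 FLI1 peaks were seen at days 7, 9, 10, 11 and 14 in 11.7%, 4.42%, 5.76%, 47.5% and 73.6%. Without chromosome 19, 44.2% of day 7 peaks had no overlap. Weighted to the width and fold rank of day 7 only peaks, 24.4% of day 0 only peaks held a day 17 FLI1 peak.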

Other observations

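The tests of depth, of the library sets and of weak FLI1 peaks were chosen after the result was seen or could be foreseen from other values; that of H3K27ac width and strength was set before its result was seen. The width of H3K27ac peaks that matched 1 to 1 between both days differed by where FLI1 was called. FLI1 at day 0 was not analysed here. FLI1 was counted over the combined span of both peaks of a pair. Wide peaks hold more FLI1 peaks by size alone, so a split by FLI1 on either day partly selects pairs that were wide at day 0 or day 7. The median log2 width at day 0 over day 7 was 0.11 for the 8132 pairs with a FLI1 peak at day 17 and not at day 7, −0.22 for the 1694 pairs with FLI1 on both days, −1.03 for the 373 pairs with FLI1 at day 7 and not at day 17, and −0.10 for the 21914 pairs without FLI1 on either day. In these groups 57.2%, 36.2%, 15.8% and 42.9% of peaks were wider at day 0.

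FLI1 regions also parted by the days on which they were present. Of the 5740 regions seen at day 11 and at neither day 14 nor day 17, 36.6% (35.4 to 37.9) lay in day 7 only and 1.86% (1.55 to 2.25) in day 0 only H3K27ac, while the largest part, 45.3%, lay in H3K27ac of both days and 16.2% in neither. Of the 7118 regions seen at days 14 and 17 and not before, 5.11% (4.63 to 5.65) lay in day 7 only, 29.6% (28.6 to 30.7) in day 0 only, 46.6% in H3K27ac of both days and 18.6% in neither. The 5740 regions include 740 that were also seen at day 7. Of these 740, 54.2% (50.6 to 57.7) lay in day 7 only H3K27ac, and 41.4% in H3K27ac of both days.

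The FLI1 lists of days 9 and 10 were shorter than that of day 7. Lower sequencing depth is argued against as the whole cause: the day 7 list thinned to the depth of day 9 and held to its p minimum kept 4072 peaks (SD over draws 12.8) against 1199, and thinned in the same way to day 10 it kept 3929 (SD 14.8) against 1591. A difference between the library sets cannot be told apart from the day, since 0 of the FLI1 days were measured in both. A true dip in FLI1 binding after DOX removal may remain as an explanation and was not tested. The yield of each immunoprecipitation was not analysed here either.

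FLI1 summits in day 7 only H3K27ac were fewer at day 17 than at day 11. Greater depth at day 11 is argued against, since after thinning day 11 to the depth of day 17 the ratio was 0.517 (0.485 to 0.552). Weak peaks at day 11, as judged by fold, are argued against as well. Of the day 11 peaks in day 7 only H3K27ac, 28.4% (26.9 to 29.9) were overlapped at day 17. The share was 66.5% (65.6 to 67.3) for those in H3K27ac of both days, weighted to the same 10 classes of day 11 fold. The q-value was not matched, so nearness to the threshold was matched only as far as fold reflects it. Of day 11 peaks in H3K27ac of neither day, 34.7% (32.4 to 37.1, not weighted) were overlapped at day 17, and of those in day 0 only H3K27ac 88.7% (86.9 to 90.4, not weighted). A low share was thus not seen at day 7 only sites alone. Peaks in neither day were more often weak, with 15.8% of the lowest and 2.18% of the highest day 11 fold class. Without weighting, their share cannot be set directly against that of day 7 only sites. H3K27ac after day 7 was not analysed here. The only input of the series is from day 0, so the later days had no input of their own. A biological cause, the control that the lists appear to share and a difference between these single libraries all stay open.

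Day 17 FLI1 peaks were more frequent in day 0 only than in day 7 only H3K27ac. Differences in width and in strength rank of the H3K27ac peaks are argued against. Day 0 only peaks weighted to the classes of the day 7 only peaks held a FLI1 peak in 24.4% of cases (SE 0.396), above the upper limit of 4.83% for day 7 only peaks. Strength was the rank of the fold within its own list. The median fold was 2.88 in the day 0 and 3.42 in the day 7 list, so absolute strength was not matched. Weak FLI1 peaks are argued against also, since above the median fold 21.8% (21.1 to 22.5) of day 17 peaks lay in day 0 only and 5.75% in day 7 only H3K27ac. Whether acetylation at these sites depends on the fusion was not tested. Nor was a part played by the control that the lists appear to share, with the only input of the series from day 0. With 1 library per day, a chance difference between libraries stays open.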
